A study of Mus musculus with 2 samples.

How the data were processed

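ChIP-seq was done on CD8 T cells isolated by negative selection from the spleens of C57BL/6 mice, per the labels' protocols. Chromatin was crosslinked and sonicated, and 1 library was made with an antiserum against Tcf1 and 1 with pre-immune rabbit serum as the control. Libraries were amplified with 18 PCR cycles and fragments of 220 to 400 bp were selected from a gel, per the labels' protocols. The number of mice behind each library is not given in the sources used here.

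The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.5 and MACS 1.4.1 and the genome build mm9, without saying what each did or with which settings. How reads that map to several places were treated, and whether duplicate reads were removed, is not given in the sources used here. The authors deposited a list of intervals in bedGraph layout with 1 score per peak, and the track line in the file names it strong peaks. The threshold behind the list, the meaning of the score and the use of the control library in peak calling are not stated in the file or labels. Peaks came from 1 Tcf1 library, so they were not pooled over replicates. No read counts, signal tracks or control peaks were used here, and depth, counting intervals for single peaks and a comparison of the libraries therefore cannot be given.

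The only gene table used here is for GRCm38.p6 (49997 genes, of which 21900 are protein-coding), while the peaks are in mm9. The builds differ: the last peak on chromosome 7 lies 6.85 Mb beyond the last gene of that chromosome in the table. Coordinates were not converted. The planned tests of peaks at promoters, of TCF/LEF and other sequence motifs, and of gene lists (T cell receptor and coreceptor, naive and memory, transcription factor, effector, inhibitory receptor, CD4 lineage, Wnt, B cell, myeloid, neuron and housekeeping genes) need mm9 annotation or sequence and were not run, and no gene was named from a coordinate. The table served only for the number of protein-coding genes per chromosome and, as approximate chromosome lengths, the end of the last gene.

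From the list, the number, width and score of peaks were summarised, with the 95% interval of a median from the binomial order statistics. This interval was not in the plan for width or score. It takes peaks as independent and does not cover differences between libraries. Positions are printed counted from 1. The count on each chromosome was set against its share of the total length with a two-sided exact binomial test, adjusted by Benjamini-Hochberg over the chromosomes, at a threshold of 0.05. The share of peaks with a neighbour within 10 kb, edge to edge, was compared with 1000 seeded random placements of the same intervals between the first and last peak of their chromosome, with a one-sided permutation p. Random placement does not avoid assembly gaps or unmappable sequence, which lowers the random share. Correlations used 100000 permutations. Named peaks followed a rule fixed before the data were examined: the 10 highest scores, and up to 10 runs of 4 or more peaks each within 10 kb of the next; all 12 such runs are given, so the last 2 of them, and the widest intervals and fullest 1-Mb windows, were chosen after their values were seen.

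The calculations were checked on simulated lists. Of 20 lists of 2827 randomly placed peaks, the clustering test called 1, and of 20 lists in which 200 peaks were moved next to another it called 20. Of 20 lists drawn by length over 21 chromosomes, the chromosome test made a call in 1, and it called chromosome 9 in 14 of 20 lists in which its density was raised 1.3 times. The random lists were placed as in the clustering test itself, so assembly gaps and mappability were not checked. The chromosome lists used lengths from the last peak and independent peaks, unlike the reported test and the clustered data.

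Alternatives set before the data were examined were merging of intervals, the peaks at or above the median score for all results but width and score, autosomes only for width, distance limits of 5 and 50 kb, and placement within 1 Mb. Autosomes only for score and for close neighbours, the peaks at or above the median score for width, lists without chromosome Y or without intervals over 1000 bp, lengths from the last peak, the peaks at or above the median width, and runs counted once were added after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.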

Results

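The series mapped where Tcf1 bound the genome of mature CD8 T cells from the spleen of wild-type C57BL/6 mice. Tcf1 is an HMG-box transcription factor of T cells that is encoded by Tcf7 and acts in the Wnt pathway. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments to which a protein is crosslinked. The study held 2 libraries, 1 precipitated with a rabbit antiserum against Tcf1 and 1 with serum of a rabbit not immunized for Tcf1. The measurement available here was the authors' list of strong peaks in mm9 coordinates, with a position and a score for each peak. Read depth is unknown, because the list gives no read counts. With 1 library per antiserum, no peak had a replicate check, and the p-values given here set this list against random positions and do not measure variation between mice.

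Tcf1 peaks were found on 21 chromosomes, the 19 autosomes and both sex chromosomes. The list held 2827 separate intervals, of which 2667 were autosomal, and none overlapped, touched or repeated another. The design text of the series states more than 3000 high-confidence peaks, so the list examined here was more than 173 peaks shorter. The peaks covered 884 kb in all. The question was where in the CD8 T cell genome Tcf1 bound, with the Cd4 silencer singled out by the submitters. Genes were not assigned to peaks, because no mm9 annotation or sequence was used here, and binding at Cd4, which encodes the coreceptor of helper T cells, was therefore not analysed here.

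The Tcf1 peaks were narrow. The median width was 276 bp, with a 95% interval of the median of 271 to 282 bp over these peaks. The middle 50% of peaks ran from 216 to 368 bp, close to the selected library fragments of 220 to 400 bp. In all, 2195 peaks (77.6%) were 200 to 500 bp wide. Broad intervals were rare: 18 peaks (0.637%) exceeded 1000 bp.

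The authors' score ranged from 4.06 to 45.69, with a median of 11.17 and a 95% interval of the median of 11.02 to 11.21. The middle 50% lay between 8.70 and 13.45. A score of 20 or more was reached by 108 peaks (3.82%), and 149 peaks (5.27%) scored under 6. What the score measures is not given in the sources used here, so its values are compared only between peaks of this list and carry no unit. Scores repeated at steps, and 498 of them (17.6%) lay within 0.0075 of a whole multiple of 2.2412, the step that took in the most peaks.

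The Tcf1 peak with the highest score lay on chromosome 16 at positions 59469679 to 59470081, with a score of 45.69 and a width of 403 bp. The next was on chromosome 13 at 97726449 to 97726880, with a score of 38.22. Chromosome 11 carried the third, at 5311545 to 5312010 with a score of 37.51, and also a peak at 105306212 to 105306620 with a score of 31.38. A peak on chromosome 1 at 43937228 to 43937613 scored 35.59. Chromosome 2 carried a pair of the top 10 peaks, at 74911239 to 74911595 with a score of 35.13 and at 156944766 to 156945258 with a score of 30.47. The other 3 lay on chromosome 9 at 88274915 to 88275387 (score 30.46), on chromosome 3 at 107649141 to 107649439 (score 30.35) and on chromosome 7 at 142733932 to 142734424 (score 29.88). All 10 were between 299 and 493 bp wide, and none was on a sex chromosome.

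Broad intervals had low scores. The 18 intervals over 1000 bp had a median score of 5.06 and a highest score of 7.82. The 1169 peaks over 200 and up to 300 bp had a median of 11.21, and the 155 peaks over 500 and up to 700 bp a median of 9.27. The widest interval covered 6120 bp of chromosome 17 from 39979801 to 39985920, with a score of 4.67. The next widest were 3994 bp on chromosome 18 from 7319768 to 7323761 (score 6.46) and 3633 bp on chromosome 14 from 45290156 to 45293788 (score 4.36). Control signal was not used here, so whether these broad intervals are particular to the Tcf1 antiserum was not tested. Across the 2827 peaks, which are not independent replicates, width and score were weakly related. Spearman's rho was -0.10 (permutation p = 1e-05, the smallest that 100000 permutations can give), and among the 2629 peaks of up to 500 bp it was -0.046 (permutation p = 0.018). Pearson's r between log2 width and score was -0.027 (permutation p = 0.149).

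**Figure D1:**
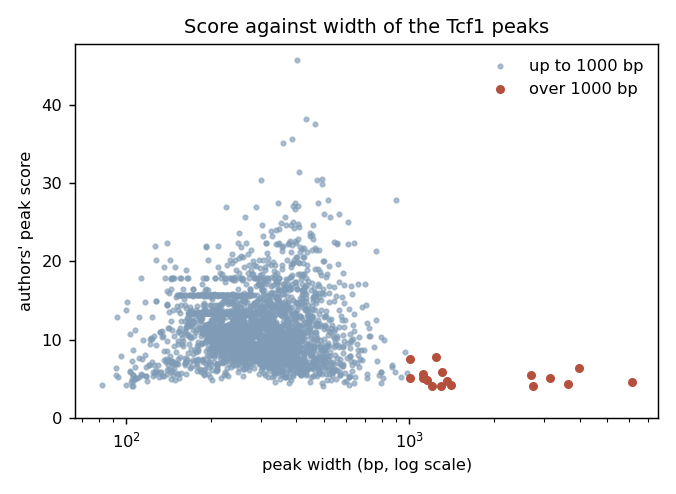
Each point is 1 of the 2827 Tcf1 peaks, with its width in bp on a log axis and the authors' score on the vertical axis. The 18 intervals over 1000 bp, drawn in red, all score 7.82 or less, while the highest score of 45.69 belongs to a peak of 403 bp.

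Chromosome 9 carried more Tcf1 peaks than its length predicts. It held 172 peaks, or 1.38 per Mb (95% exact binomial interval 1.19 to 1.60), against 1.04 per Mb over the 21 chromosomes. This was 1.33 times the number expected from length (exact binomial test, two-sided, Benjamini-Hochberg adjusted p = 0.0023). This and the other chromosome tests take peaks as independent. Close peaks break this, so the p-values are likely too small and the intervals too narrow. With each run of peaks within 10 kb counted once, chromosome 9 held 151 places and 1.29 times the expected number (exact binomial test, adjusted p = 0.014). That test kept chromosome Y, whose approximate length raised the ratios of the other chromosomes. Runs were not counted once with Y left out, so whether chromosome 9 would pass under both changes is not known. Chromosome 11 followed with 1.28 peaks per Mb and 1.23 times the expected number, which did not pass the threshold (exact binomial test, adjusted p = 0.066). Chromosome 19 had 1.26 peaks per Mb (exact binomial test, adjusted p = 0.347). The lowest autosomal density was 0.872 per Mb on chromosome 18 (exact binomial test, adjusted p = 0.347).

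Chromosome Y also passed, with 7 peaks and 0.0742 times the expected number (exact binomial test, adjusted p = 1.8e-30). This value rests on lengths taken from the last gene of each chromosome in a GRCm38 gene table, which for Y was 31.6 times the position of the last Y peak; for the other chromosomes this ratio lay between 0.955 and 1.02. The long Y also raised the ratios of the other chromosomes. Without Y, 1 of the 20 chromosomes passed, chromosome 9 with 1.29 times the expected number (exact binomial test, adjusted p = 0.020). Chromosome 11 then had 1.19 times the expected number (exact binomial test, adjusted p = 0.167). Among the peaks at or above the median score, with Y included, chromosome 9 held 84 peaks and 1.29 times the expected number, against 1.33 times for all peaks, and its call ended (exact binomial test, adjusted p = 0.198). Of the 7 peaks on Y, 5 were 118 to 253 bp wide with scores of 6.55 to 11.73, and 2 were broad, at 2734 and 2692 bp, with scores of 4.13 and 5.47.

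**Figure D2:**
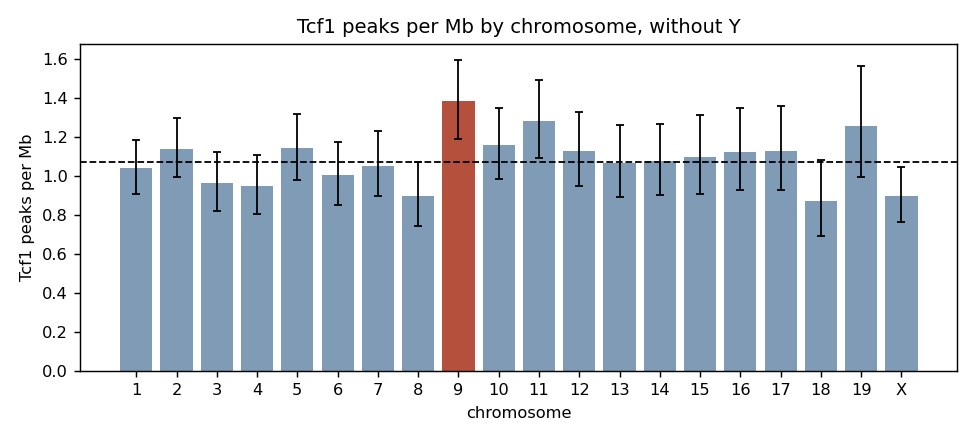
Bars give Tcf1 peaks per Mb for the 19 autosomes and X, with lengths from the last gene of a GRCm38 table and 95% exact binomial intervals; the dashed line is the mean of 1.07 per Mb, and red marks an adjusted p under 0.05. Chromosome 9 is highest at 1.38 per Mb and chromosome 18 lowest at 0.872.

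Chromosome X held 153 peaks, and their distribution along it was uneven. Its density was 0.896 peaks per Mb, 0.863 times the expected number (exact binomial test, adjusted p = 0.328). Without Y in the test, this was 0.836 times (exact binomial test, adjusted p = 0.167). A block from 120 to 123 Mb held 64 of the 153 peaks (41.8%), or 21.3 per Mb, and the rest of the chromosome held 89 peaks, or 0.531 per Mb. The block was delimited after its counts were seen, as adjoining 1-Mb windows of 10 or more peaks. Its peaks had a median score of 8.46, against 11.21 for the other X peaks. Among its 35 gaps under 20 kb between neighbouring peaks, 16 pairs were equal within 2%. Draws of autosomal gaps had a median of 6 pairs, a 95th percentile of 11 and a highest value of 24. The draws were not matched to the block's gap sizes, and this test was chosen after the pattern was seen, so it does not show that spacings recur. When each run of peaks within 10 kb was counted once, X held 101 places and 0.629 times the expected number, which passed (exact binomial test, adjusted p = 3.4e-06).

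**Figure D3:**
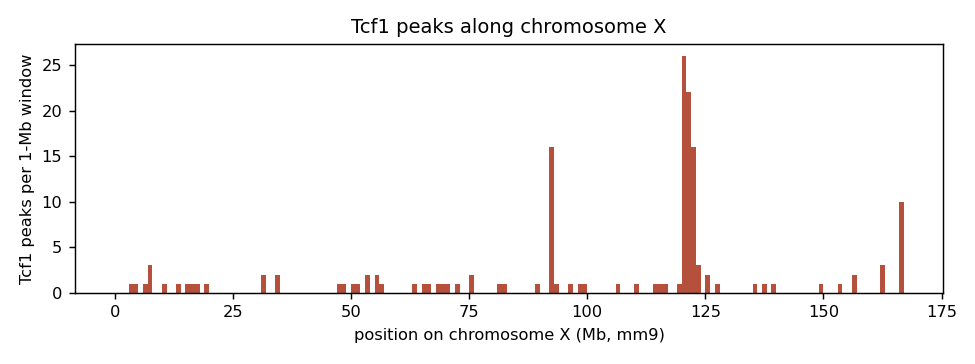
Bars count the Tcf1 peaks in each 1-Mb window of chromosome X (mm9 position in Mb on the horizontal axis). The 3 adjoining windows from 120 to 123 Mb hold 26, 22 and 16 peaks, the window from 92 to 93 Mb holds 16 and that from 166 to 167 Mb holds 10.

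Tcf1 peaks lay close to one another more often than random positions would. In all, 462 peaks (16.3%) had another peak within 10 kb, against a mean of 2.31% (95% range 1.56 to 3.11%) in 1000 random placements of the same intervals on their chromosomes. This was 7.07 times the random share (permutation p = 0.001, one-sided, the smallest that these placements can give). The median distance to the nearest other peak was 151 kb, against 309.9 kb (95% range 292 to 329.6 kb) at random. On the autosomes alone, 14.5% of peaks had a neighbour within 10 kb, 6.29 times the random share (permutation p = 0.001). When each peak was moved by at most 1 Mb, which keeps regional density, the random share rose to 4.61% and the excess was 3.55 times (permutation p = 0.001).

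**Figure D4:**
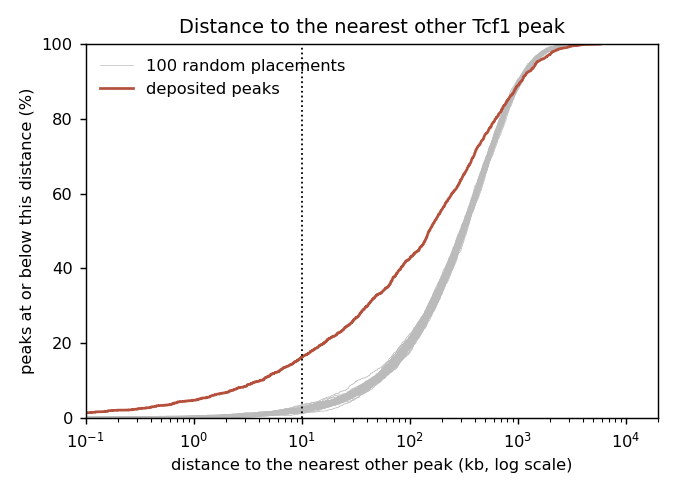
The red line gives the percentage of the 2827 Tcf1 peaks whose nearest other peak lies at or below the distance on the log axis, and the grey lines give 100 random placements; distances under 0.1 kb are drawn at 0.1 kb. At the dotted line of 10 kb the peaks stand at 16.3%, and random placements average 2.31%.

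Counting neighbours within 10 kb as 1 place left 2560 places, of which 195 held 2 or more peaks. The 12 runs of 4 or more peaks held 67 peaks, and 8 of these runs were autosomal. Chromosome 1 carried 5 peaks between 130497943 and 130511870, with scores of 6.99 to 9.70. Chromosome 11 carried 5 peaks between 98978127 and 98998156, with scores of 8.84 to 22.28, and 4 between 46202797 and 46218831, with scores of 6.00 to 10.12. Among the runs of 4, that on chromosome 2 between 113962527 and 113979269 had the highest median score, 15.81. The run on chromosome 14 between 56903269 and 56915942 had a median of 12.09, that on chromosome 12 between 74694360 and 74706603 a median of 10.37, and that on chromosome 6 between 48668535 and 48683379 a median of 9.18. A run on chromosome 2 between 98502342 and 98507577 differed in shape, with 4 intervals of 621 to 1358 bp and a median score of 7.21. Whether the control serum gave the same signal there was not tested.

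Chromosome X carried the other 4 runs. The longest held 16 peaks in 44.4 kb between 92123499 and 92167890, all of 184 to 344 bp, with scores of 8.34 to 20.17. A run of 9 between 166427101 and 166444693 was made of broader intervals, with a median width of 797 bp, a widest of 3131 bp and a median score of 5.89. Control signal was not examined for this run or for the run of 16. The remaining pair, each of 4 peaks, lay inside the 120 to 123 Mb block, between 120863766 and 120881618 and between 122344410 and 122362680.

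Peaks were also crowded when counted in 1-Mb windows, which include the runs above. Of the 1-Mb windows, 80 held 5 or more peaks, against a mean of 15.5 (95% range 9 to 23) in 1000 random placements, and the fullest window of any placement held 9. The fullest autosomal windows were 130 to 131 Mb on chromosome 3 with 12 peaks and a median score of 12.58, and 98 to 99 Mb on chromosome 11 with 10 peaks and a median score of 12.18. The window from 123 to 124 Mb on chromosome 9 held 9 peaks. Windows on chromosome 10 (21 to 22 Mb), chromosome 11 (46 to 47 Mb) and chromosome 18 (75 to 76 Mb) held 8 each. The windows were chosen for their counts after these were seen. They were not recounted with each run as 1 place, so crowding at 1 Mb was not separated from the runs.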

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

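Of 20 alternatives to 5 results, 14 kept the direction and the side of the threshold, or stayed within 1.5 times a count or within the interval of a median. Those that merged overlapping or touching intervals could change nothing, since there were none. The excess of close neighbours passed under each of its 6 alternatives (permutation p = 0.001 each): 11.2% of peaks within 5 kb against 1.20% at random, 33.0% within 50 kb against 10.7%, and 7.24% within 10 kb among the peaks at or above the median score against 1.18%. Those at or above the median score were 1423 peaks, which follows from its construction, and their median width was 252 bp. Peaks at or above the median width had a median score of 10.35. Against the 2 chromosomes that passed in the test by length (9 and Y), 1 passed among the peaks at or above the median score (Y), 1 without chromosome Y (9) and 1 with lengths from the last peak in the list (9). The call on Y depends on the length used: with lengths from the last peak, which leave out any part of Y beyond its own peaks by construction, its ratio was 2.26 (exact binomial test, adjusted p = 0.172), and whether Y held few peaks for its mm9 length was not tested; the call on chromosome 9 ended on fewer peaks (84 of its 172) with its ratio at 1.29, against 1.33 for all peaks. With runs counted once, 3 passed (9, X and Y). This was among the alternatives counted as kept, because only the number of calls was compared, although the call on X was new. Non-N chromosome lengths, and the alternatives for promoters, motifs and gene lists, were not run because no mm9 sequence or annotation was used here. No paired analysis was possible because each antiserum has 1 library. The list gives no reads, so a place without a peak is not shown to lack Tcf1.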

Other observations

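The tests of recurring gaps, of score steps and of background on chromosome X were chosen after the pattern was seen; those of gene density and of the X scores were written before their results.

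Tcf1 peaks were denser on autosomes with more protein-coding genes per Mb. Across the 19 autosomes of this 1 list, peaks per Mb and protein-coding genes per Mb had Pearson's r = 0.48 (permutation p = 0.036, 95% bootstrap interval 0.13 to 0.77) and Spearman's rho = 0.50 (permutation p = 0.030); both adjusted values were 0.036. Without chromosomes 7 and 11, farthest from the median gene density, r was 0.55 (permutation p = 0.023). Chromosome 7 had the highest gene density, 13.97 per Mb, and 1.05 peaks per Mb, and chromosome 9 had 9.65 genes and 1.38 peaks per Mb. The hypothesis that gene density sets part of the difference between autosomes fits this test, and chromosomes of 1 library are not independent experiments.

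The first pattern is the crowding of 64 peaks between 120 and 123 Mb of chromosome X. A candidate explanation is multi-copy sequence, whose near-identical copies share reads and would repeat the same spacing of peaks. Among the 35 gaps under 20 kb between neighbouring midpoints there, 16 pairs were equal within 2%. In 10000 draws of as many gaps from the 300 autosomal ones, the median was 6 and the 95th percentile 11 (permutation p = 0.0041), though the highest draw reached 24. The draws were not matched to the block's gap sizes. A different spread of gap sizes there could also give more equal pairs, so the excess does not show that spacings recur. Peaks at 120656569 to 120656934 and 120877950 to 120878315 shared a width of 366 bp and a score of 8.84. They were the only such pair among the 64 peaks, and how many pairs chance would give was not computed. No biological explanation was tested, and how shared reads were placed is not given in the sources used here, so the block may still hold real sites in each copy.

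The second pattern is a step structure in the score. Of the 2827 scores, 498 (17.6%) lay within 0.0075 of a whole multiple of 2.2412, a step fitted to these scores. In 200 lists in which each distinct score was shifted by up to 0.3, so that repeated scores stayed repeated, the best step took in a median of 202 peaks and at most 373. The commonest values were 13.45 (175 peaks), 11.21 (163) and 15.69 (79), and the multiples 5, 6 and 7 took 418 of the 498. The equal spacing fits the hypothesis that the score is a small whole number over a background that is constant for these peaks; if so, many listed peaks may rest on few reads at their summit. The scale of the score is not stated, so the reads themselves remain unknown.

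The third pattern is that chromosome X, outside its crowded windows, held few peaks. A peak was present in 55 of 171 1-Mb windows of X (32.2%) and in 1363 of 2470 autosomal windows (55.2%; Fisher's exact test, two-sided, p = 7.0e-09), and the lowest autosome, chromosome 4, had 44.6%. Low gene density is argued against as the whole cause, since X lay below the 95% prediction interval of the autosomal regression on genes per Mb, 41.4 to 66.2%. In windows of 3 or fewer peaks, 41 of 63 X peaks (65.1%, exact 95% interval 52.0 to 76.7%) lay on a score step. Among autosomal peaks, 393 of 1921 did (20.5%, 18.7 to 22.3%, Fisher's exact test p = 7.6e-14). The highest autosome, chromosome 14, had 35.9%. A lower background on X would give this if the steps are a constant background, but the share does not show why X held few peaks. The X peaks compared here were also narrower (median width 212 against 261 bp), and the shares were not matched for width. Fewer copies of X remain open: the median score of these X peaks was 1 step above that of the autosomal peaks (13.45 against 11.21, a difference of 2.24 with a 95% bootstrap interval of 0.0 to 2.28; permutation p = 0.00061), and off the steps it was 11.3 on 22 X peaks against 10.49. A lower score had been predicted for fewer copies and was not seen. The interval of the difference reaches 0 and what the score measures is not stated, so the scores do not decide it. Fewer copies of X could also lower the background there, so the steps do not tell a lower background and fewer copies apart. Mappability was not tested, and the sex of the mice is not in the labels. The list held 7 peaks on Y, but whether their reads came from Y was not tested.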
